A study of Arabidopsis thaliana with 33 samples.

How the data were processed

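RNA was measured in whole seedlings of Arabidopsis thaliana, ecotype Columbia, grown in a greenhouse at 22 °C in a cycle of 12 h light and 12 h dark and collected at 16 days, per the labels. The 33 samples fall into 11 genotypes with 3 replicates each: wild type (WT), the mutants sdg25, sdg26, atx1 and clf, the double mutants sdg25 sdg26, atx1 sdg26, clf sdg26 and ldl1 ldl2, and the triple mutants ldl1 ldl2 sdg25 and ldl1 ldl2 sdg26. Each sample was hybridised alone, labelled with Cy3, to one array of an Agilent slide with up to 4 arrays, from 2 µg of total RNA purified with Trizol and RNeasy columns, per the labels. Nothing in the sources used here says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays, 3 per genotype, limits the precision.

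The deposited scanner tables hold the intensity of each spot on a linear scale, made by the authors with Agilent Feature Extraction 10.7.3.1 per the file headers, with the software's background subtraction already applied to the processed signal. The array design in those headers names an older build of the genome than the reference used here, so no coordinates are printed. The deposited series matrix holds values that the authors computed from the same arrays. Its 43663 rows include all 43603 non-control probes. Set against the log2 processed intensity of the same array, its columns correlated at r = 0.9952 to 0.9999, so they are taken as log2 values in the same direction. Their medians were all 9.04 and their sorted values differed by at most 0.00296, as after quantile normalization; the method and any centring of single probes are not given in the sources used here. These deposited log2 values served as an alternative only.

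Each array held 43803 non-control spots for 43603 probes, 50 of them spotted more than once and averaged. Probes were named through the RefSeq accession in the array files and the RefSeq genes of assembly TAIR10.1. Of 36188 probes with such an accession, 34358 matched a gene, which gave 25433 genes, 6940 of them with more than 1 probe. For these the probe with the highest mean level over all arrays was used. SDG25 had no matched probe. Control spots and spots with an outlier flag were left out. The main values are log2 of the processed intensity minus the 75th percentile of the array. A gene entered the tests if its probe was well above background, by the scanner software's own flag, on all 3 arrays of at least 1 genotype. This kept 19965 genes and removed 5468.

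A gene that no array of a genotype measured well above background with any of its probes has only a bound there. It is given as "at least N-fold", the mean of the brighter genotype against the mean of, per array, the higher of the lowest signal among probes well above background and the dim probe's own signal. For AG, a second probe of ATX1 and CLF within scan day 1 the bound is that of the single probe, set after the values had been seen. No fold is given where both genotypes were below background. Means of lists take all values as measured. No probe was saturated.

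Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend in the prior variance) in 1 model with a mean for each of the 11 genotypes, so that all share the estimate of the spread with 22 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison, two-sided, and a gene passes when its value is under 0.05. Errors given with log2 differences are standard errors (SE) of this model, each for 3 arrays against 3 unless stated otherwise. Tables were read with data.table (version 1.17.8) and figures drawn with matplotlib 3.10.9 in Python 3.11.15. The comparisons are each mutant against WT, each combined mutant against the parent line that lacks only the sdg26 or sdg25 mutation, the sdg26 effect averaged over 5 backgrounds (WT, sdg25, atx1, clf and ldl1 ldl2), and the interaction of sdg26 with each other mutation and of sdg25 with ldl1 ldl2. An interaction is the effect in the mutant background minus the effect in the WT background.

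The arrays were scanned on 4 days, which held 13, 4, 8 and 8 arrays. Day 1 held all 11 genotypes, and the WT arrays were scanned on day 1 (2 arrays) and day 2 (1 array). The scan day is therefore partly tied to the contrast of mutants with WT. Counts, means of lists and many of the named genes are given also from a model with scan day as a block (19 residual degrees of freedom), and some within each scan day that held both genotypes. Within day 1 that is 1 mutant array, or 2 of sdg25 sdg26, against 2 of WT. Within day 2 it is 1 against 1, for sdg25, clf sdg26 and ldl1 ldl2 sdg26 alone. Those arrays are also part of the model, so these values are not independent of it and have no test of their own.

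Gene lists fixed before the data were examined, 22 in all, were tested with camera in limma with a preset correlation of 0.01 and again with an estimated correlation, adjusted over 210 tests for mutants against WT and over 252 for the other comparisons. They are flowering repressors (15 of 16 members measured), floral integrators and promoters (14 of 22), autonomous pathway and FLC chromatin repressors (13 of 13), floral organ identity genes (8 of 10), class I KNOX genes (4 of 4), seed maturation genes (11 of 20), histone methylation and demethylation machinery (29 of 30), morning-phased clock genes (12 of 12), evening-phased clock genes (9 of 9), light-harvesting antenna genes (20 of 20), salicylic acid and immunity genes (22 of 24), jasmonate genes (30 of 30), heat shock genes (17 of 23), cold, drought and abscisic acid genes (22 of 22), phosphate starvation genes (11 of 12), dark and sugar starvation genes (8 of 8), flavonoid and anthocyanin genes (14 of 17), glucosinolate genes (22 of 22), cell division genes (19 of 19), root markers (7 of 14), anther, pollen and ovule markers (2 of 12) and reference genes (10 of 11). A list needed 3 measured members, so the anther, pollen and ovule markers were not tested as a set. The comparisons, lists, tests, alternatives and the rule for named genes were all set before the data were examined, except where the text says otherwise.

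Named genes were chosen by this rule. The mutated genes and FLC, SOC1 and FT are given in every mutant whatever their p. For each mutant against WT, up to 8 genes with the highest and 8 with the lowest log2 change were eligible among those past the threshold whose 3 mutant arrays all lay on the same side of the 3 WT arrays and whose probe was well above background on all of them. Up to 4 genes measured in all arrays of 1 genotype and none of the other, and up to 10 list members past the threshold, were eligible as well. For parent lines, interactions and the averaged effect up to 4 genes in each direction and up to 6 list members were eligible. For the averaged effect a gene had to be separated in the same direction, and well above background, in each of the 5 backgrounds. From the eligible genes the text mainly names those that kept their call without each single array; this choice was made after the values were seen. Transposons are left out.

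Comparisons against the same WT arrays share their chance values. The correlation of log2 changes between 2 mutants was therefore set beside that of 100 simulated pairs of unchanged genotypes against shared WT arrays, without scan-day effects. What the design alone gives with scan day as a block was computed from the model, after the values had been seen. On data simulated without scan-day effects for sdg26 against WT with 19965 genes, the model recovered 23.9% of genes changed 1.5-fold, 58.2% changed 2-fold and 90.9% changed 4-fold. False calls made up 4.17%. For the interaction of sdg26 with sdg25 it recovered 10.4%, 38.8% and 81.8% of the same sizes with 4.4% false, and for the averaged sdg26 effect 83.6%, 95.5% and 100% with 5.1% false. With simulated scan-day effects and the block, it recovered 23.9%, 58.2% and 93.9% for sdg26 against WT with 4.88% false.

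The alternatives were normexp background correction with an offset of 50, quantile normalization, no filter on dim probes, the mean of all probes of a gene, the deposited series matrix, the replicate number as a block, the slide as a fixed and as a random block, scan day as a block, and each array left out in turn. The files hold the median and not the mean of each spot's pixels, so normexp used the median signal and the median background. On 4 arrays some spots had backgrounds so high that signal minus background reached -30944; spots whose background was flagged were therefore given the median background of their array, after which the lowest difference was -9.5. A fit on the 17 arrays of scan days 1 and 2 alone and a test of the histone list without the mutated genes were added after the data had been seen.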

Results

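Gene expression was measured on 33 one-colour arrays of whole 16-day seedlings of Arabidopsis thaliana, 3 for each of 11 genotypes. The mutated genes act on histones. SDG25 (ATXR7) and ATX1 are H3K4 methyltransferases, SDG26 (ASHH1) is a SET-domain protein, CLF is an H3K27 methyltransferase of Polycomb repressive complex 2, and LDL1 and LDL2 are LSD1-like histone demethylases. The comparisons ask which transcripts each mutation changed and whether sdg26 or sdg25 changed those of another mutant further. Between 65.4% and 78.2% of probes were well above background on an array, and the 75th percentile of processed intensity ran from 2394 to 4963. Replicates of a genotype correlated across genes at r = 0.971 to 0.994; genes are not independent replicates.

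The transcripts of the mutated genes were examined first. SDG26 fell in all 5 lines that carry sdg26, with log2 differences of -2.97 ± 0.47 in sdg26 (adjusted p = 0.0104), -4.43 in sdg25 sdg26 (3.75e-06), -3.96 in atx1 sdg26 (8.28e-05), -4.68 in clf sdg26 (4.11e-07) and -4.40 in ldl1 ldl2 sdg26 (1.64e-06). CLF was lower in clf (4.7e-12), where 1 of 3 arrays measured it well above background; the fitted -5.80 rests on signals below background on the others and gives no size. It was at least 51.9-fold lower in clf sdg26 (2.89e-13). LDL1 was at least 164-fold, 170-fold and 155-fold lower in ldl1 ldl2, ldl1 ldl2 sdg25 and ldl1 ldl2 sdg26 (1.03e-22, 9.26e-23 and 2.66e-22), and LDL2 at least 15.1-fold, 15.6-fold and 14.2-fold lower (1.68e-17, 9.5e-18 and 1.85e-17). The ATX1 probe used here differed by -0.68 ± 0.25 in atx1 (0.166) and by -0.23 in atx1 sdg26 (0.599). Its place relative to the insertions is not given, so it leaves the labels open. A dimmer ATX1 probe passed in these lines alone, which favours the labels. SDG25 had no matched probe, so sdg25 labels were not checked this way.

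With scan day as a block the SDG26 differences were -3.14, -4.40, -4.12, -4.87 and -4.64 in the same order, and within scan day 1 they were -3.23, -4.03, -4.07, -4.61 and -4.03. The clf array of day 1 did not measure CLF well above background; it was at least 93.4-fold lower there. SDG26 in sdg26 missed the threshold without sdg26 replicate 1 (adjusted p = 0.0527). In the mutants that do not carry its mutation, none of the measured genes SDG26, ATX1, CLF, LDL1 and LDL2 passed the test against WT in limma.

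**Figure D1:**
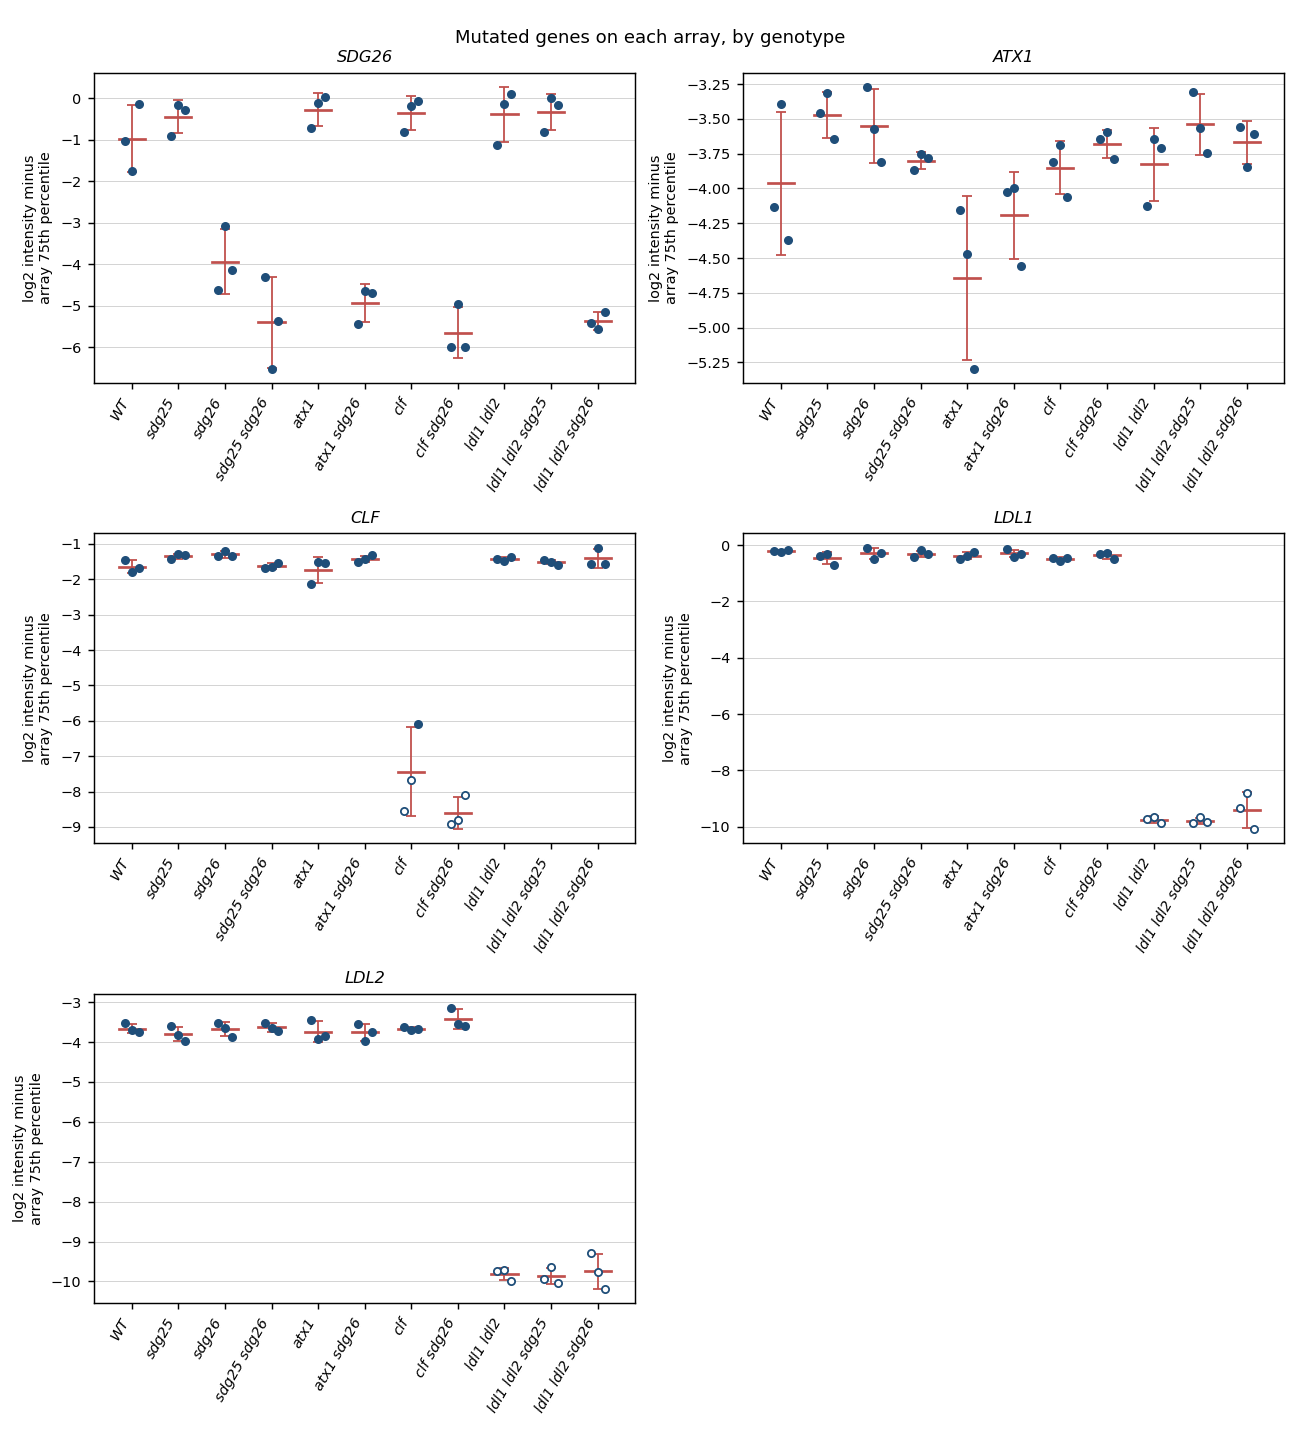
Normalised log2 level of SDG26, ATX1, CLF, LDL1 and LDL2 on each array, by genotype; filled points were well above background, open points were not, and the red bars give the mean and SD of 3 arrays. SDG26 is lower in the 5 lines that carry sdg26.

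FLC, the MADS-box repressor of flowering, moved in opposite directions in the single mutants. It fell by 2.42 ± 0.18 on the log2 scale in sdg25 (adjusted p = 7.63e-09) and by 2.47 in atx1 (4.63e-09), and rose by 1.28 in sdg26 (0.00314) and by 1.95 in clf (7.88e-08). In combination with sdg26 it stood at 2.77 in clf sdg26 (4.69e-11) and 2.36 in ldl1 ldl2 sdg26 (3.22e-09). The doubles sdg25 sdg26 and atx1 sdg26 differed from WT by only -0.04 and -0.12 (0.96 and 0.718). FLC in ldl1 ldl2 was at 0.53 (0.105) and in ldl1 ldl2 sdg25 at 0.40 (0.18). With scan day as a block the 10 values were -2.44, 1.29, -0.01, -2.46, -0.11, 1.96, 2.76, 0.54, 0.42 and 2.36, in the order sdg25, sdg26, sdg25 sdg26, atx1, atx1 sdg26, clf, clf sdg26, ldl1 ldl2, ldl1 ldl2 sdg25 and ldl1 ldl2 sdg26. Within scan day 1 they were -2.12, 1.38, 0.37, -2.33, 0.28, 2.1, 3.19, 0.32, 0.53 and 2.82, and within day 2 they were -2.90 in sdg25, 2.19 in clf sdg26 and 1.79 in ldl1 ldl2 sdg26. All 6 FLC calls held without each single array. The 2 doubles near WT stood at 0.19 and 0.11 without WT replicate 3 (0.62 and 0.701). FLC in ldl1 ldl2 passed without ldl1 ldl2 replicate 1 (0.0287), without WT replicate 3 (0.0156) and with the mean of its probes (0.65, adjusted p = 0.0173), and in ldl1 ldl2 sdg25 without WT replicate 3 (0.0273).

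SOC1, a floral integrator that FLC represses, fell by 0.98 ± 0.16 in clf sdg26 (adjusted p = 0.00114) and by 1.15 in ldl1 ldl2 sdg26 (0.000106). The values with scan day as a block were -1.02 and -1.21, within day 1 they were -1.14 and -1.55, and within day 2 -0.94 and -0.80. SOC1 in atx1 was higher by 0.84 (0.0221, 0.80 with the block, 0.83 within day 1). That call ended without atx1 replicate 1 (0.0669), 2 (0.0538) or 3 (0.0791) or WT replicate 2 (0.0622), with normexp (0.0558) and with slides as a fixed block (0.153), which also ended the call in clf sdg26 (0.09). In the other mutants SOC1 differed by 0.56 in sdg25 (0.114), -0.30 in sdg26 (0.348), 0.40 in sdg25 sdg26 (0.356), 0.38 in atx1 sdg26 (0.223), 0.23 in clf (0.421), 0.14 in ldl1 ldl2 (0.636) and 0.36 in ldl1 ldl2 sdg25 (0.191). FT, which encodes the florigen, was not well above background on any WT array. It was at least 3.96-fold higher in clf (0.0015) and at least 4.67-fold higher in clf sdg26 (0.000582). In ldl1 ldl2 sdg26 FT passed as lower (0.0421), but it lay below background in both genotypes there, so no fold is given. That call ended without WT replicate 1 (0.102) or 2 (0.16) or ldl1 ldl2 sdg26 replicate 1 (0.0509), 2 (0.185) or 3 (0.137), and with normexp (0.469), quantile normalization (0.29), the mean of probes (0.134) and the series matrix (0.291). The other adjusted p-values for FT were 0.997 in sdg25, 0.304 in sdg26, 0.959 in sdg25 sdg26, 0.66 in atx1, 0.828 in atx1 sdg26, 0.553 in ldl1 ldl2 and 0.902 in ldl1 ldl2 sdg25.

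**Figure D2:**
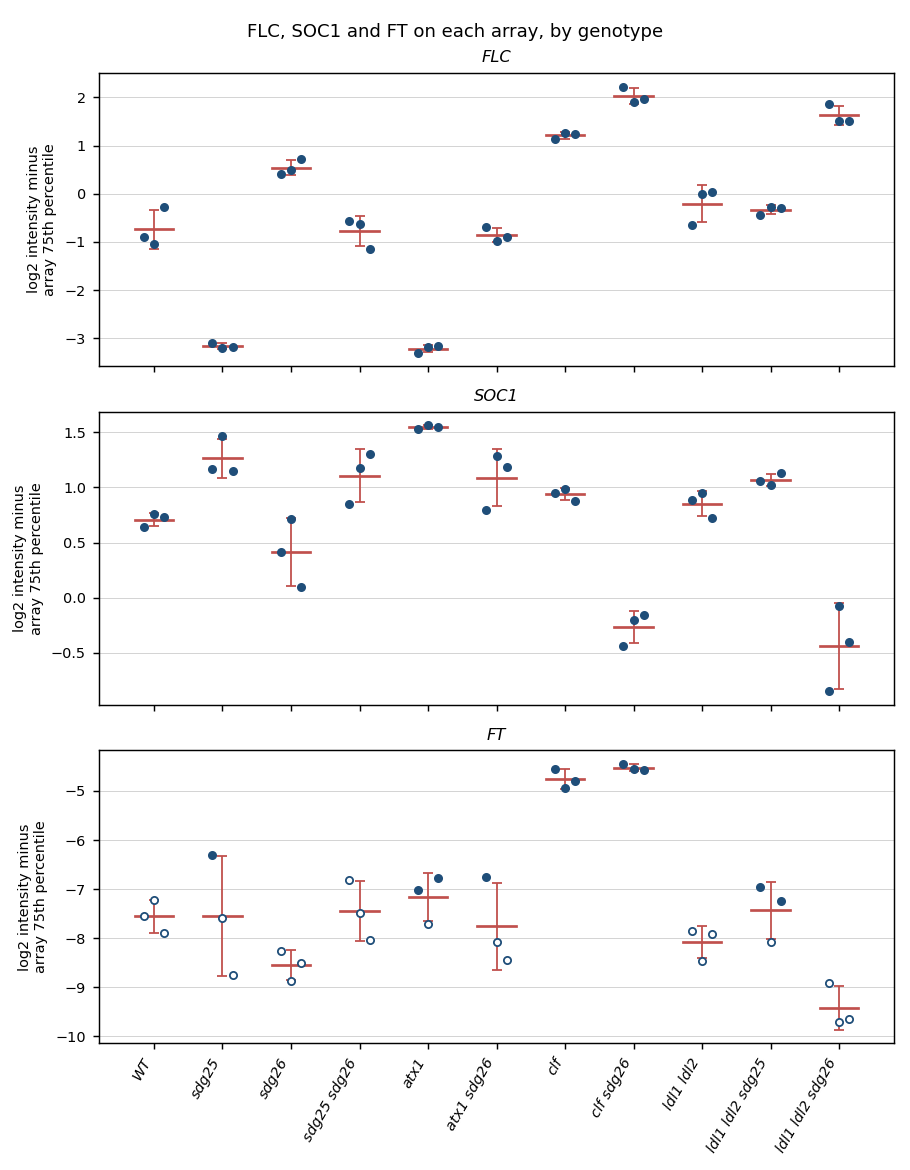
Normalised log2 level of FLC, SOC1 and FT on each array, by genotype; filled points were well above background, open points were not, and the red bars give the mean and SD of 3 arrays. FLC means run from -3.21 in atx1 to 2.04 in clf sdg26.

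Seedlings of sdg25 had lower transcript levels of MRD1, a gene of unknown function, by 3.08 ± 0.32 on the log2 scale (adjusted p = 2.65e-06, -3.17 with scan day as a block), beside the fall of FLC. UNE15 fell by 1.67 ± 0.16 (5.5e-07, -1.71), the methyl esterase gene MES8 by 1.49 ± 0.19 (9.32e-05, -1.61) and AT5G56370 by 1.83 (0.000107). Among genes that rose were AT4G19520 at 1.63 ± 0.26 (0.00139) and PIP5K5, a phosphatidylinositol phosphate kinase, at 1.1 ± 0.18 (0.00206, 1.16). Within scan days 1 and 2 MRD1 stood at -3.70 and -3.08, and UNE15 at -1.51 and -1.67. In limma 131 genes changed, 34 up and 97 down, 52 of them by at least 2-fold; with scan day as a block the count was 434, which held all 131, and with normexp it was 48, 7 up and 41 down. Of 23 named genes that passed, 11 kept their call without each of the 6 arrays. Leaving out WT replicate 2 gave 73 genes, WT replicate 3 324, sdg25 replicate 2 56 and sdg25 replicate 3 79.

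The sdg26 seedlings had the lowest count of called genes, 42, while 3290 genes had an unadjusted p under 0.05, beside 2661 in sdg25 with 131 called. Beside the fall of SDG26 and the rise of FLC, GA20OX3, an enzyme of gibberellin synthesis, was at least 3.06-fold higher (adjusted p = 0.0233). VATG3, a subunit of the vacuolar proton pump, was higher by 1.25 (0.0185), and MRD1 fell by 1.69 (0.0233, -1.84 with scan day as a block, -1.92 within day 1). Each of these calls was lost without sdg26 replicate 1, at 0.0542, 0.0527 and 0.101, and without 2 or 3 further arrays. Normexp ended the call of GA20OX3 (0.283) and slides as a fixed block that of MRD1. The called genes were 19 up and 23 down, 21 of them by at least 2-fold, and the block called 87, of which 37 were among the 42. The split was 3 up and 8 down with normexp, 18 up and 52 down with quantile normalization and 18 up and 51 down with the series matrix. FLC alone of 17 named genes kept its call without each array. The count was 7 without WT replicate 2, 222 without WT replicate 3, 1 without sdg26 replicate 1 and 7 without sdg26 replicate 3.

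In the double sdg25 sdg26 the receptor kinase gene HSL1 fell by 1.76 ± 0.11 (adjusted p = 4.57e-11, -1.78 with scan day as a block and -1.78 within day 1). MRD1 fell by 3.1 (2.46e-06, -3.25 within day 1) and AT5G56370 by 1.42 (0.00374), and AT1G66650 was at least 2.93-fold lower (2.46e-06). AT4G38300 rose by 2.07 ± 0.29 (0.000233), UGT73C6, a glucosyltransferase, by 1.61 ± 0.27 (0.00346) and AT5G44980 by 1.42 (0.000403). Normexp ended the call of AT5G44980 (0.19) and the mean of probes that of AT5G56370 (0.173). In all 137 genes changed, 54 up and 83 down, 62 by at least 2-fold; the scan-day block called 446, including all 137, and normexp 36, 10 up and 26 down. Of 18 named genes, 10 kept their call without each array. The count was 75 without WT replicate 1, 62 without WT replicate 2, 215 without WT replicate 3, 73 without sdg25 sdg26 replicate 2 and 53 without sdg25 sdg26 replicate 3.

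The atx1 mutant showed lower NF-YA2, a subunit of a CCAAT-binding factor, by 1.58 ± 0.22 (adjusted p = 0.000545, -1.49 with scan day as a block, -1.43 within day 1), and lower MRD1 by 2.51 (0.000196, -2.42 within day 1). ACS6, an ACC synthase of ethylene production, rose by 1.38 ± 0.21 (0.00249, 1.35, 1.24). These genes and FLC were the 4 of 23 named genes that kept their call without each array. The test found 119 genes, 56 up and 63 down, 59 by at least 2-fold; the block called 284, among them 108 of the 119, and normexp 23, 5 up and 18 down. Arrays whose omission moved the count most were WT replicate 2 (23) and 3 (615) and atx1 replicates 1, 2 and 3 (14, 57 and 14).

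In atx1 sdg26 MRD1 fell by 2.96 (adjusted p = 2.5e-05, -3.1 with scan day as a block, -2.74 within day 1) and SDG26 fell as given above. An ankyrin-repeat gene listed as ANK rose by 2.4 ± 0.39 (0.00629, 2.72 with the block), a call that normexp ended. These 3 of 21 named genes kept their call without each array. WRKY38, a transcription factor of salicylic acid defence, was at least 3.81-fold higher (0.0381), and the floral organ gene PI was higher by 1.00 (0.0192). The first call was lost in 5 of 6 omissions of an array, at most at 0.219 without atx1 sdg26 replicate 2, and the second without that array (0.122) or replicate 3 (0.0692). Normexp and slides as a fixed block ended both calls, the mean of probes the first (0.145), and quantile normalization and the series matrix the second (0.0512 and 0.0518). The 96 called genes, 39 up and 57 down with 41 of at least 2-fold, became 215 with the block, 86 of them shared, and 6 up with 46 down under normexp and 28 up with 66 down after quantile normalization. Omitting WT replicate 1 left 61 genes, WT replicate 2 29, WT replicate 3 253, and atx1 sdg26 replicates 1, 2 and 3 left 55, 10 and 61.

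Floral organ identity genes rose in clf. By the probe used here, which no WT array measured well above background, the carpel and stamen gene AG was at least 203-fold higher (adjusted p = 1.34e-12). SEP3 rose by 3.67 ± 0.18 (2.81e-13, 3.51 with scan day as a block, 3.55 within day 1) and PI by 2.63 ± 0.19 (8.76e-10, 2.54, 2.46). The other AG probe was well above background on 1 of 3 WT arrays. SHP2, an ovule and fruit gene, was at least 22.5-fold higher (1.81e-08), HB40, a homeodomain-leucine zipper gene, at least 26.7-fold (7.2e-06), and SWEET10, a sugar transporter, rose by 4.81 ± 0.23 (2.81e-13, 4.74, 4.82). MAM3, of aliphatic glucosinolate synthesis, fell by 2.84 ± 0.28 (2.13e-07, -2.72, -2.68), and MRD1 by 3.39 (1.27e-07, -3.96 within day 1). The test called 329 genes, 150 up and 179 down, 183 of at least 2-fold; the block called 458, including 270 of them, and normexp 179, 63 up and 116 down. Of 27 named genes 18 kept their call without each array; the count was 174 without WT replicate 2, 530 without WT replicate 3, and 181, 109 and 157 without clf replicates 1, 2 and 3.

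The same floral genes stood high in clf sdg26. AG was at least 181-fold higher by the same probe (adjusted p = 1.29e-12). SEP3 was higher by 3.37 (1.09e-12, 3.30 with the block, 3.01 within day 1 and 3.47 within day 2), PI by 2.61 (8.55e-10, 2.66, 2.29 and 3.03) and SWEET10 by 4.42 (7.76e-13, 4.38, 4.01 and 4.82). SHP2 was at least 20.2-fold higher (2.95e-08), and TCP12, a TCP factor of axillary buds, rose by 2.29 ± 0.25 (1.53e-06, 2.38). MAM3 fell by 2.38 (5.08e-06, -2.26) and MRD1 by 3.48 (6.35e-08). Limma called 360 genes, 171 up and 189 down, 164 of at least 2-fold; the block called 1016, which held all 360, and normexp 136. Of 27 named genes, 22 kept their call without each array; the count was 194 without WT replicate 2, 617 without WT replicate 3 and 207, 172 and 144 without clf sdg26 replicates 1, 2 and 3.

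In ldl1 ldl2 the largest fall outside the mutated genes was in AT3G05160, at -6.65 ± 0.23 on the log2 scale (adjusted p = 2.95e-17, -6.43 with scan day as a block, -6.30 within day 1). AT1G78760 rose by 3.05 ± 0.31 (1.69e-06), a monodehydroascorbate reductase gene listed as MDHAR by 2.27 ± 0.38 (0.000978, 2.44, 2.57) and PBS3, of salicylic acid synthesis, by 2.09 ± 0.36 (0.00152, 2.26, 1.90). PI rose by 1.78 ± 0.19 (3.08e-06, 1.70, 1.84), AP3, its partner in petals and stamens, was at least 1.21-fold higher (0.00698, a call that normexp ended), and TRI at least 8.62-fold higher (0.000293). MRD1 fell by 1.99 (0.000772, -1.80 within day 1). Limma called 517 genes, 265 up and 252 down, 214 of at least 2-fold; the block called 1292, 613 up and 679 down, 499 of the 517 among them, and normexp 253. Of 27 named genes, 18 kept their call without each array; the count was 342, 209 and 1146 without WT replicates 1, 2 and 3 and 169 without ldl1 ldl2 replicate 2.

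The triple ldl1 ldl2 sdg25 had the most called genes. AT3G05160 fell by 6.96 (adjusted p = 9.5e-18, -6.74 with the block, -6.80 within day 1), and AT1G78760 rose by 3.56 (4.65e-08), MDHAR by 2.83 (3.43e-05, 3.00, 2.62), PBS3 by 2.44 (0.000131, 2.60, 2.11) and PI by 2.31 (2.61e-08, 2.22, 2.01). FUS3, a B3 factor of seed maturation, was at least 3.35-fold higher (0.0041). SDC, an F-box gene silenced by DNA methylation, fell by 2.41 (0.00154), and MRD1 by 2.39 (3.85e-05, -2.30 within day 1). MEA, a Polycomb gene, was higher by 3.95 ± 0.93 (0.0118, 4.67), a call that ended without ldl1 ldl2 sdg25 replicate 2 (0.0559). The test called 1217 genes, 602 up and 615 down, 429 of at least 2-fold; the block called 2178, 1127 of them shared, and normexp 668, 241 up and 427 down. Of 26 named genes, 17 kept their call without each array; the count was 600 without WT replicate 2 and 359 without ldl1 ldl2 sdg25 replicate 2.

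In ldl1 ldl2 sdg26 AT3G05160 fell by 6.78 (adjusted p = 1.85e-17, -6.60 with the block, -6.59 within day 1 and -6.60 within day 2). AT1G78760 rose by 3.33 (1.81e-07), AT1G02770 by 2.52 (1.81e-07), the methyl esterase gene MES18 by 2.60 (0.00028), MDHAR by 2.43 (0.000346, 2.60, 2.65 and 2.66), PBS3 by 2.15 (0.000985, 2.29, 1.81 and 2.41) and PI by 1.4 (8.44e-05, 1.37, 1.09 and 1.47). MRD1 fell by 2.00 (0.000509). Limma called 334 genes, 211 up and 123 down, 191 of at least 2-fold; the block called 943, including 333 of them, and normexp 170. Of 27 named genes, 18 kept their call without each array; the count was 213 and 167 without ldl1 ldl2 sdg26 replicates 1 and 2.

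**Figure D3:**
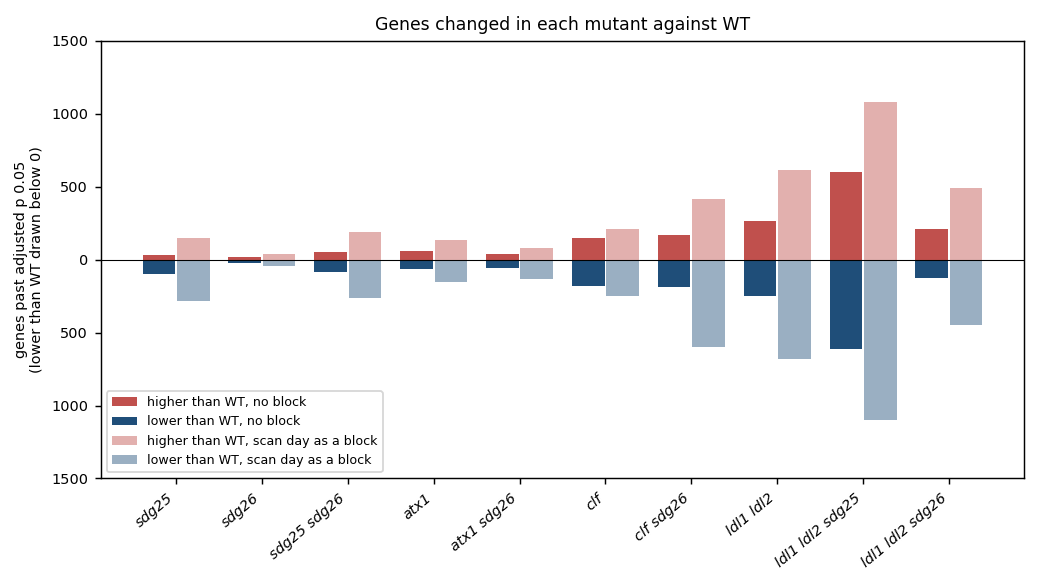
Number of genes higher (upward bars) and lower (downward bars) than WT in each mutant, without a block and with scan day as a block. Counts without a block run from 42 to 1217.

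MRD1 (-3.48 to -1.69) was lower and OVA1, an aminoacyl-tRNA synthetase gene, higher (1.78 to 2.2) in all 10 mutants, the only such calls. LCV1, AT3G19550 and GA20OX3 were higher in 9 mutants, and ACS6 and AT1G19960 in 8; AT5G10620 and AT5G35740 were lower in 8. All 10 tests share 3 WT arrays, so a WT level off by chance shows in each. For OVA1 these ran from -2.49 to 0.06, into the mutant range (from -0.03). OVA1 in sdg25 missed the threshold without WT replicate 1 (adjusted p = 0.0658) or sdg25 replicate 2 (0.056), in sdg26 without WT replicate 1 (0.0768) or any sdg26 array (at most 0.125), in sdg25 sdg26 without WT replicate 1 (0.132) or replicate 2 or 3 of the double (0.0614 and 0.0968), in atx1 without atx1 replicate 3 (0.0752) and in atx1 sdg26 without atx1 sdg26 replicate 2 (0.0838). Normexp ended the OVA1 calls in sdg25, sdg26, sdg25 sdg26 and atx1, and slides as a fixed block those in sdg26, atx1 and atx1 sdg26. Across the mutants 1744 genes were called at least once and 805 in at least 2 mutants.

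Flowering repressors, a list that holds FLC, had a mean of -0.42 on the log2 scale in sdg25 (camera adjusted p = 0.00179, adjusted p = 0.0478 with an estimated correlation). There 2 of 15 measured members fell, and 4 adjusted over the list alone. The mean was -0.48 with scan day as a block, -0.45 within day 1 and -0.50 within day 2. Its FLC-clade member MAF5 was lower, at -1.45 (0.0178), a call lost in 5 of 6 omissions of an array, at most at 0.0809 without sdg25 replicate 2. The list was higher in ldl1 ldl2 sdg26, where 3 members rose (3 adjusted over the list alone, mean 0.39, camera adjusted p = 0.00607, adjusted p = 0.0921 with an estimated correlation, 0.35 with the block, 0.29 within day 1 and 0.37 within day 2). Floral organ identity genes rose in clf, 7 of 8 members and 8 adjusted over the list alone, with a mean of 3.37 (1.62e-25, 6.97e-06 with an estimated correlation, 3.13 with the block, 3.21 within day 1). The clf sdg26 seedlings gave 7 of 8, 8 over the list alone and a mean of 3.23 (2.76e-28, 5.43e-06 with an estimated correlation, 3.12, 3.00 within day 1 and 3.32 within day 2).

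For floral organ identity genes the means were 0.91 in ldl1 ldl2 (3 up), 0.94 in ldl1 ldl2 sdg25 (1 up) and 0.57 in ldl1 ldl2 sdg26 (1 up, 1 down), with camera adjusted p = 0.00102, 0.00147 and 0.0182; adjusted over the list alone 3, 2 and 3 rose and 1 fell in the last. The means were 0.67, 0.71 and 0.43 with the block, and 0.42, 0.42 and 0.11 within day 1, with 0.75 in ldl1 ldl2 sdg26 within day 2; with an estimated correlation, adjusted p = 0.192, 0.203 and 0.47. In ldl1 ldl2 sdg26 the call ended without WT replicate 3 (0.0984) or ldl1 ldl2 sdg26 replicate 3 (0.078), and normexp ended it there and in ldl1 ldl2 sdg25. The list was also called in atx1 (mean 0.58, camera adjusted p = 0.0197) and atx1 sdg26 (0.42, 0.0326), but not with an estimated correlation (adjusted p = 0.47 and 0.558), with scan day as a block (0.0785 and 0.0774) or without WT replicate 3 (0.123 and 0.149). PI alone passed, also adjusted over the list alone. PI in atx1, at 0.91 (0.0318), lost its call in 4 of 6 omissions and with normexp, quantile normalization, the series matrix and slides as a fixed block. The list means were 0.35 and 0.19 with the block and 0.35 and 0.07 within day 1, normexp turned the atx1 sdg26 mean to -0.10, and the call in atx1 sdg26 also ended without its replicate 3 (0.0744).

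Salicylic acid and immunity genes, 22 of them measured, had a mean above WT in every mutant, with camera adjusted p from 6.71e-05 in ldl1 ldl2 sdg25 to 0.0188 in clf sdg26. None of these calls held with an estimated correlation, where the lowest adjusted p = 0.641 and the highest 0.885. In the order sdg25, sdg26, sdg25 sdg26, atx1, atx1 sdg26, clf, clf sdg26, ldl1 ldl2, ldl1 ldl2 sdg25 and ldl1 ldl2 sdg26, the means were 0.36, 0.59, 0.47, 0.52, 0.57, 0.61, 0.38, 0.42, 0.79 and 0.46. They were 0.43, 0.77, 0.57, 0.69, 0.75, 0.79, 0.45, 0.59, 0.96 and 0.66 with the block and 0.68, 0.51, 0.48, 0.37, 0.79, 1.13, 0.37, 0.59, 0.70 and 0.63 within day 1. Within day 2 they were 0.40, 0.78 and 0.66 in sdg25, clf sdg26 and ldl1 ldl2 sdg26. The members that passed numbered 0, 0, 0, 1, 1, 4, 3, 2, 4 and 2, all higher; adjusted over the list alone 0, 3, 3, 3, 4, 4, 3, 4, 7 and 4 were higher and 1 was lower in ldl1 ldl2 and in ldl1 ldl2 sdg25. Except in ldl1 ldl2 sdg25, the call ended without WT replicate 3, with adjusted p from 0.0569 to 0.194, and in 8 of those 9 mutants also without an array of the mutant. These were replicate 2 in atx1 (0.22), replicates 1 and 2 in clf sdg26 (0.107 and 0.057) and replicate 1 in sdg25 (0.279), sdg25 sdg26 (0.134), atx1 sdg26 (0.158), clf (0.134), ldl1 ldl2 (0.155) and ldl1 ldl2 sdg26 (0.0597).

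Cell division genes were lower in sdg25 sdg26 (mean -0.27, camera adjusted p = 0.00672), atx1 (-0.25, 0.0292), clf (-0.23, 0.0464), clf sdg26 (-0.32, 0.00413) and ldl1 ldl2 (-0.23, 0.0385). None of these calls held with an estimated correlation (adjusted p = 0.814, 0.893, 0.905, 0.814 and 0.897). Of 19 members 0, 0, 0, 1 and 2 fell, and 0, 4, 3, 4 and 3 adjusted over the list alone. The means were -0.32, -0.35, -0.34, -0.37 and -0.34 with the block, and -0.29, -0.28, -0.30, -0.45 and -0.56 within day 1, and -0.28 in clf sdg26 within day 2. All 5 calls ended without WT replicate 1 (0.189, 0.316, 0.365, 0.0717 and 0.341). Those in atx1, clf and ldl1 ldl2 also ended without WT replicate 3 (0.0761 each) and without replicate 1 of the mutant (0.055, 0.153 and 0.601), and that in clf without clf replicate 2 (0.0751). Histone methylation and demethylation genes, a list that holds the mutated genes, were called in clf sdg26, ldl1 ldl2, ldl1 ldl2 sdg25 and ldl1 ldl2 sdg26, with means of -0.49, -0.48, -0.47 and -0.65 (camera adjusted p = 0.0348, 0.0338, 0.0341 and 0.00185), and adjusted p = 0.363, 0.363, 0.363 and 0.0921 with an estimated correlation. The mutated genes account for most or all of these means: without them, a test chosen after the values were seen, the means were -0.12, 0.03, 0.04 and 0.02 and none was called (0.438, 0.601, 0.526 and 0.554). Among all 29 members 3, 4, 3 and 4 fell and 0, 0, 1 and 0 rose; adjusted over the list alone 4, 4, 5 and 5 fell and 1, 2, 1 and 1 rose.

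Dark and sugar starvation genes were higher in ldl1 ldl2 (mean 0.71, camera adjusted p = 0.00618, 0.71 with the block, 1.13 within day 1) and ldl1 ldl2 sdg25 (0.63, 0.0292, 0.64, 1.2). None of 8 members passed over all genes and 5 were higher adjusted over the list alone in each; with an estimated correlation adjusted p = 0.641 and 0.814. Both calls ended without WT replicate 2 (0.096 and 0.273), and that in ldl1 ldl2 sdg25 without WT replicate 1 (0.128) or its own replicate 1 (0.113). Morning-phased clock genes were higher in sdg25 (0.27, 0.0104, 0.26 with the block, 0.29 within day 1 and 0.24 within day 2), sdg26 (0.26, 0.0479, 0.18, 0.26) and sdg25 sdg26 (0.22, 0.0419, 0.15, 0.13), with no member past the threshold and 1 in sdg26 adjusted over the list alone. The block ended the calls in sdg26 and sdg25 sdg26 (0.0561 and 0.121), WT replicate 3 decided all 3 (0.0761, 0.156 and 0.157 without it), WT replicate 2 those of sdg26 and sdg25 sdg26 (0.108 and 0.18), and with an estimated correlation adjusted p = 0.474, 0.649 and 0.641. Without sdg26 replicates 1 and 3 the sdg26 call ended as well (0.17 and 0.0595), as did that of sdg25 sdg26 without its replicates 2 and 3 (0.0558 and 0.214). Cold, drought and abscisic acid genes were higher in the same mutants by 0.33, 0.31 and 0.26 (0.00538, 0.0165 and 0.00688, 0.28, 0.23 and 0.24 with the block, 0.17, 0.34 and 0.20 within day 1 and 0.33 in sdg25 within day 2). None of 22 members passed in these 3 mutants, 2 and 1 did in sdg25 and sdg26 adjusted over the list alone, and with an estimated correlation adjusted p = 0.226, 0.363 and 0.288. In sdg26 the call ended without WT replicate 1 (0.0909), WT replicate 3 (0.055) or sdg26 replicate 1 (0.063), and in sdg25 sdg26 without WT replicate 1 (0.0512) or its replicate 3 (0.101).

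Light-harvesting antenna genes had means of 0.37 in atx1 (camera adjusted p = 0.0148) and 0.53 in clf (0.000914) with no member called, also adjusted over the list alone; with an estimated correlation adjusted p = 0.893 and 0.814. The means were 0.06 and 0.22 with the block and 0.17 and 0.26 within day 1, and they turned to -0.04 and -0.02 after quantile normalization and in the series matrix. The call in atx1 ended with the block (0.47) and without WT replicate 1 (0.0815) or atx1 replicate 3 (0.134). Jasmonate genes were higher in clf (0.52, 0.0236, 0.55 with the block, 1.14 within day 1) and ldl1 ldl2 sdg26 (0.43, 0.00538, 0.52, 1.04, and 0.45 within day 2), with no member called either way and adjusted p = 0.897 and 0.814 with an estimated correlation. The first call ended without WT replicate 1 (0.0909), WT replicate 3 (0.0761) or clf replicate 1 (0.498) and the second without ldl1 ldl2 sdg26 replicate 1 (0.674). Floral integrators were higher in clf, where 3 of 14 members rose and 4 rose and 3 fell adjusted over the list alone (0.40, 0.0341, 0.49, 0.44); the call ended without clf replicate 1 (0.0654) or WT replicate 3 (0.114), and with an estimated correlation adjusted p = 0.204. In ldl1 ldl2 sdg26 flavonoid genes (0.52, 0.0163, 0.49, 0.20 and 1.08 within days 1 and 2, 1 member adjusted over the list alone) and glucosinolate genes (0.22, 0.0385, 0.20, 0.14 and 0.22, 2 members, 4 adjusted over the list alone) were higher, with adjusted p = 0.641 and 0.865 with an estimated correlation. Both calls ended without WT replicate 3 (0.295 and 0.279), and the glucosinolate call without replicates 1 and 3 of the mutant (0.0731 and 0.239).

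The remaining lists were not called by camera in any mutant. No autonomous pathway gene, evening-phased clock gene, heat shock gene, root marker or reference gene passed in any mutant, and the reference genes had means between -0.04 and 0.09. Seed maturation genes gave FUS3, at least 2.94-fold higher in ldl1 ldl2 (adjusted p = 0.012), 3.35-fold in ldl1 ldl2 sdg25 (0.0041) and 3.00-fold in ldl1 ldl2 sdg26 (0.0123). The first of these calls was lost without WT replicate 2 (0.0525) or ldl1 ldl2 replicate 2 (0.06), and normexp ended the first and the third (0.0552 and 0.0546). Among class I KNOX genes STM was lower in ldl1 ldl2 sdg25, at -1.08 (0.0343, 0.0538 with the block, lost in 5 of 6 omissions, at most at 0.156 without ldl1 ldl2 sdg25 replicate 2), a call that normexp, the mean of probes and slides as a fixed block ended as well. Of the phosphate starvation genes PHO1;H1 was lower in the same mutant. Neither of the 2 measured anther, pollen and ovule markers passed in any mutant.

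**Figure D4:**
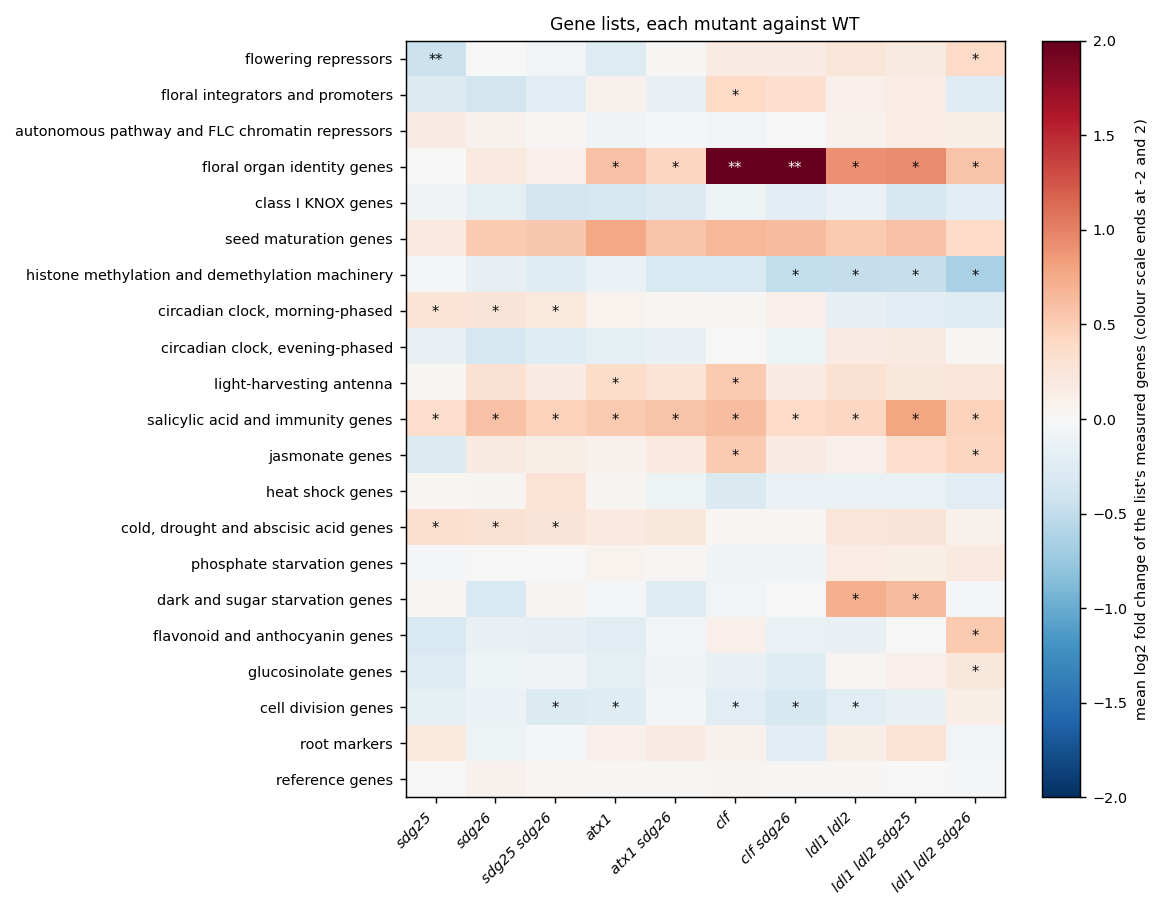
Mean log2 difference from WT of the measured members of each gene list (rows) in each mutant (columns), on a colour scale that ends at -2 and 2; 1 star marks lists called by camera with the preset correlation, 2 stars those called also with an estimated correlation. Floral organ identity genes in clf (3.37) and clf sdg26 (3.23) lie beyond the end of the scale.

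The lines that differ only by sdg26 were then compared. FLC rose with sdg26 in the sdg25 background by 2.38 ± 0.18 (adjusted p = 5.42e-09, 2.43 with scan day as a block, 2.50 within day 1), in atx1 by 2.35 (1.4e-08, 2.35, 2.61) and in ldl1 ldl2 by 1.83 (1.61e-06, 1.82, 2.50). In clf it was higher by 0.83 ± 0.18, which did not pass (0.165, 0.79, 1.09 within day 1 and 0.73 within day 3). SOC1 fell with sdg26 by 1.21 in clf (0.000828, -1.21, -1.39 within day 1 and -1.04 within day 3) and by 1.3 in ldl1 ldl2 (0.000153, -1.32, -1.74 within day 1 and -1.13 within day 4), and did not pass in sdg25 at -0.16 or in atx1 at -0.46 (1 each). SDG26 differed by -4.95 in sdg25 (6.22e-07, -4.74, -4.52), -4.66 in atx1 (3.29e-06, -4.66, -4.73), -5.30 in clf (4.55e-07, -5.32, -5.19) and -4.98 in ldl1 ldl2 (1.61e-06, -5.06, -4.29). RABA6b, a Rab GTPase gene, fell by 1.02 in clf (0.00278) and by 1.04 in ldl1 ldl2 (0.00207), the latter lost without ldl1 ldl2 sdg26 replicate 3 (0.0532). HSL1 fell by 1.77 in sdg25 (4.48e-11, -1.78, -1.62). AT1G77960 and AT4G29990 rose by 1.63 and 0.86 in clf (0.00193 each); the mean of probes ended the first call, and normexp and slides as a fixed block the second. The FLC differences within days 3 and 4 in atx1 were 2.19 and 2.26, and within day 4 in ldl1 ldl2 1.48. Slides as a fixed block ended the SOC1 call in clf.

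Called genes numbered 20 in sdg25 sdg26 against sdg25 (16 up, 4 down), 2 in atx1 sdg26 against atx1 (FLC and SDG26), 6 in clf sdg26 against clf (3 up, 3 down) and 12 in ldl1 ldl2 sdg26 against ldl1 ldl2 (7 up, 5 down). With scan day as a block they were 51, 36 (7 up and 29 down), 8 and 17, and all but 2 genes of the last comparison were among these. With normexp they were 6 up and 4 down, 4 in all, 1 up and 3 down, and 6 in all. Quantile normalization and the series matrix each gave 15 up and 8 down in the first comparison. There the count was 12 and 9 without sdg25 replicates 1 and 3 and 10 without sdg25 sdg26 replicate 3. In the second it was 4 without atx1 replicate 2. In the last it was 6, 5 and 7 without ldl1 ldl2 replicates 1, 2 and 3 and 6, 5 and 4 without those of ldl1 ldl2 sdg26. Flowering repressors rose as a group in sdg25 sdg26 against sdg25 (mean 0.36, 0.40 with the block, 0.41 within day 1, camera adjusted p = 5.28e-06, adjusted p = 0.0032 with an estimated correlation), where FLC passed and 4 members did adjusted over the list alone. They did so in atx1 sdg26 against atx1 (0.29, 0.29, 0.29, 7.84e-06, 0.0032 with an estimated correlation), with FLC alone past the threshold either way. Floral integrators fell in ldl1 ldl2 sdg26 against ldl1 ldl2 (mean -0.37, -0.44, -0.49, 0.00292, 0.039 with an estimated correlation). SOC1 alone passed either way, and FT (-1.34) lay below background. Of other lists there, cell division genes (mean 0.37, 0.37, 0.43) and flavonoid genes (0.68, 0.69, 0.76, 4 members adjusted over the list alone) were higher and dark and sugar starvation genes lower (-0.75, -0.77, -0.45), with adjusted p = 0.438, 0.406 and 0.406 with an estimated correlation.

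Averaged over the 5 backgrounds, sdg26 raised FLC by 1.73 ± 0.08 (adjusted p = 5.61e-14, 1.74 with scan day as a block) and lowered SOC1, at -0.68 ± 0.07 (2.46e-06), SDG26, at -4.57 ± 0.21 (5.61e-14), and RABA6b, at -0.85 ± 0.07 (2.44e-08). AT4G38300 rose by 1.29 ± 0.13 (9.63e-07), AT1G77960 by 1.06 (1.1e-06) and CYP79F2, of glucosinolate synthesis, by 0.69 (0.00319), and AT2G17150 fell by 0.65 (4.57e-06). All 10 named genes kept their call without each of the 30 arrays; the mean of probes ended that of AT2G17150 (0.079) and normexp that of CYP79F2 (0.0509). The test called 200 genes, 99 up and 101 down, 11 of at least 2-fold, and 485 with the block, 210 up and 275 down, and 87 with normexp. Flowering repressors had a mean of 0.16 (0.17 with the block, 0.16 within day 1, camera adjusted p = 0.00142, adjusted p = 0.039 with an estimated correlation), with FLC alone past the threshold. Floral integrators had a mean of -0.19 (-0.20 with the block, 0.018), with 1 member lower and 2 adjusted over the list alone, and adjusted p = 0.156 with an estimated correlation.

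The effect of sdg25 was also compared in other backgrounds. With sdg25 added to ldl1 ldl2, UNE15 fell by 1.47 (adjusted p = 1.34e-05, -1.44, -1.85 and -1.12 within days 1, 3 and 4), AT1G66650 by 2.18 (0.000128) and AT1G77960 by 1.81 (0.000185), and PIP5K5 rose by 1.05 (0.00614). FLC differed by -0.13 (1) with the probe used. With scan day as a block these values were the same. The PIP5K5 call ended without ldl1 ldl2 sdg25 replicate 1 (0.0945) or ldl1 ldl2 replicate 3 (0.0827). Against sdg26, sdg25 sdg26 had lower HSL1 by 1.80 (2.77e-11, -1.80, -1.74 within day 1 and -2.03 within day 4), lower FLC by 1.32 (0.000378, -1.3, -1.01 and -1.63, ended by slides as a fixed block, 0.0734) and lower AT3G56210 by 1.09 (0.000267, -1.15). The counts were 38 in the first comparison (15 up, 23 down, 83 with the block, 7 up and 17 down with normexp) and 17 in the second (2 up, 15 down, 37 with the block, 2 up and 6 down with normexp, 5 up and 13 down after quantile normalization). In the first, 23 and 22 genes were left without ldl1 ldl2 replicates 2 and 3 and 24 and 20 without ldl1 ldl2 sdg25 replicates 1 and 3. In the second, any omission left 8 to 10, namely 10, 9 and 8 without sdg26 replicates 1, 2 and 3 and 9, 10 and 10 without those of sdg25 sdg26.

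Interactions were tested directly. HSL1 had an interaction of sdg26 with sdg25 of -1.80 ± 0.15 (adjusted p = 7.58e-08, -1.81 with the block). Its group means were 2.74 ± 0.07 in WT, 2.74 ± 0.17 in sdg25, 2.78 ± 0.19 in sdg26 and 0.98 ± 0.06 in the double (SD, n = 3 each, limma). FLC had an interaction of sdg25 with ldl1 ldl2 of 2.29 ± 0.25 (3.86e-05, 2.31), and AT3G56210 passed in both, at -1.4 (0.0023, -1.51) and -1.53 (0.00047, -1.59). MRD1 passed in the second at 2.69 ± 0.45 (0.0203, 2.77), lost in 7 of 12 omissions and with slides as a fixed block. A high WT level can give it. For sdg26 with sdg25 limma called 4 genes, 2 up and 2 down (6 up and 2 down with the block, 2 with normexp, both lower). The count was 8 without WT replicate 1, 11 without WT replicate 3, and 2 without any 1 array of sdg26, sdg25 replicates 1 or 2 or sdg25 sdg26 replicates 1 or 2. For sdg25 with ldl1 ldl2 it called 3 (6 with the block, 5 without WT replicate 3). No gene passed in limma for sdg26 with atx1, clf or ldl1 ldl2, with unadjusted p under 0.05 for 1252, 2165 and 2612 genes. With scan day as a block these counts were 0, 1 and 0. Without WT replicates 1, 2 and 3 they were 1, 1 and 2 for atx1, 2, 1 and 1 for clf and 2, 1 and 0 for ldl1 ldl2. Camera called 22 list and interaction pairs, none with an estimated correlation.

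Changes against WT were then set side by side between mutants. In chance simulations with shared WT arrays and no effect of genotype or scan day, 2 mutants correlate at r = 0.499 to 0.503 across genes, so they exclude nothing about scan day. Over all 45 pairs the observed r ran from 0.451, for sdg25 sdg26 with ldl1 ldl2 sdg26, to 0.90, and 43 pairs lay above the 0.5 that the design alone gives. After a block for scan day r ran from 0.387 to 0.88, where the design alone gives 0.474 to 0.559 and 33 pairs lay above the value of the design. Without the block r was 0.82 for clf with clf sdg26, 0.90 for ldl1 ldl2 with ldl1 ldl2 sdg25, 0.79 for ldl1 ldl2 with ldl1 ldl2 sdg26, 0.88 for atx1 with atx1 sdg26, 0.71 for sdg25 with sdg25 sdg26 and 0.69 for sdg25 with atx1, and with it 0.798, 0.88, 0.787, 0.816, 0.657 and 0.608. Pairs without a shared mutation came near these values, such as atx1 with clf at 0.801 and sdg26 with atx1 at 0.795 (0.702 and 0.679 with the block), and sdg25 with sdg26 at 0.744 (0.688). Covariances were 0.181, 0.227, 0.158, 0.200, 0.0989 and 0.124, beside simulated values of 0.0490 to 0.0494. Genes called up in both numbered 106, 225, 134, 21, 13 and 5, where independent lists give 1.28, 7.99, 2.80, 0.109, 0.092 and 0.0954. Genes called down in both numbered 82, 199, 65, 21, 33 and 9, where independent lists give 1.69, 7.76, 1.55, 0.18, 0.403 and 0.306. With 3 WT arrays the controls are too few to split between the compared mutants, so part of each excess may come from the shared controls, and part from scan day, since r fell with the block in all 6 of the pairs named first, from 0.882 to 0.816 for atx1 with atx1 sdg26.

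The sdg26 effect was also compared between backgrounds with no shared arrays, over 19960 genes. The correlation of log2 differences was 0.236 between atx1 and ldl1 ldl2 (0.288 with scan day as a block), 0.278 between clf and ldl1 ldl2 (0.147), 0.220 between sdg25 and clf (0.113), 0.137 between atx1 and clf (0.193), 0.126 between sdg25 and ldl1 ldl2 (0.0844) and 0.0727 between sdg25 and atx1 (0.0902). With the effect in the WT background it was 0.0063 for sdg25 (0.169), 0.124 for atx1 (0.0852), -0.339 for clf (-0.0706) and -0.271 for ldl1 ldl2 (-0.0465). No correlation passed 0.0475 in simulations without scan day. With the block the design alone gives values from -0.082 to 0.082, and those of the WT background with clf and with ldl1 ldl2, -0.082 and -0.08, are as low as the values seen there. The ldl1 ldl2 effect correlated at 0.615 between the WT and sdg25 backgrounds (0.646), 0.112 between WT and sdg26 (0.381) and 0.480 between sdg25 and sdg26 (0.622). The clf effect correlated at 0.104 between WT and sdg26 (0.362), the atx1 effect at 0.315 (0.304), and the sdg25 effect at -0.199 between WT and sdg26 (0.0475), 0.219 between WT and ldl1 ldl2 (0.269) and 0.139 between sdg26 and ldl1 ldl2 (0.136).

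The arrays did not fall into genotypes on the main axis of variation. The first principal component, with 29.3% of the variance, separated the 17 arrays of scan days 1 and 2 from the 16 of days 3 and 4, and the second held 11.8%. The residual SD fell from 0.251 to 0.185 with scan day as a block. All called genes kept their sign with the block in every comparison. Within scan day 1 so did all compared with WT, but those arrays helped to call them, so it is no test.

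**Figure D5:**
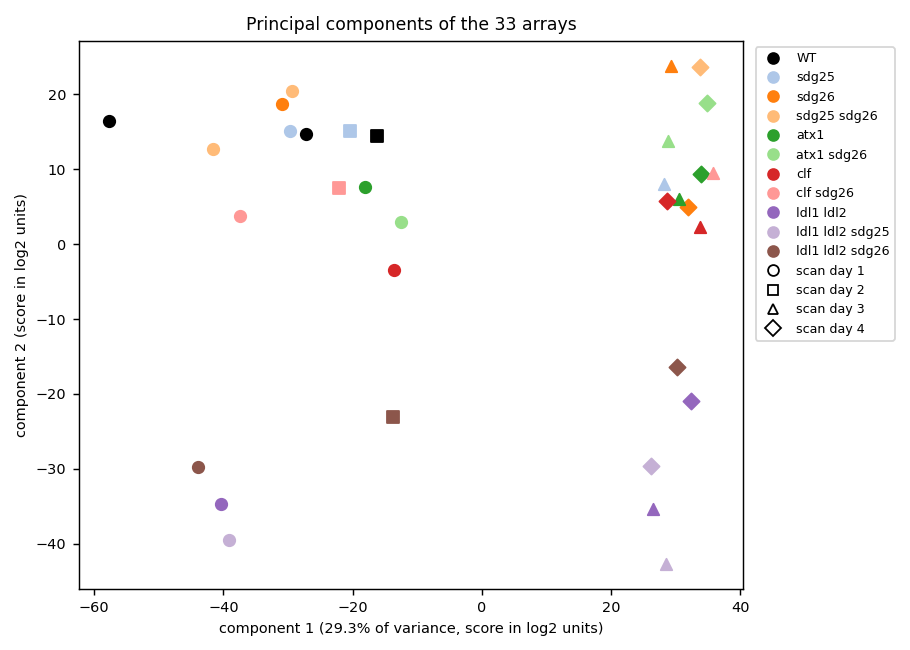
The 33 arrays on the first 2 principal components (29.3% and 11.8% of variance), with colour for genotype and shape for scan day. Arrays of scan days 1 and 2 lie at or below -12.5 on the first component and those of days 3 and 4 at or above 26.2.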

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

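The tests of the FLC pattern below were chosen after its values had been seen; the interaction tests that single out the other genes were planned. FLC was lower in sdg25 by 2.42 on the log2 scale and stood at 0.40 in ldl1 ldl2 sdg25, and the interaction of sdg25 with ldl1 ldl2 was 2.29 ± 0.25 (adjusted p = 3.86e-05, limma). A scan-day effect is argued against, because the interaction kept its call and size with scan day as a block (2.309, adjusted p = 6.64e-05); on the arrays of days 1 and 2 alone it was 2.61 and missed the threshold with fewer arrays (0.481). A fault of a single probe is argued against as well, because the 3 FLC probes gave 2.14, 1.836 and 2.29. Triple-mutant arrays without the sdg25 mutation would leave the other sdg25 genes unmoved, but these 130 genes had a median signed difference of 0.429 between ldl1 ldl2 sdg25 and ldl1 ldl2, 115 of them in the same direction, beside 0.849 in sdg25 and at most 0.042 in 99 random sets. That ldl1 ldl2 may remove the need of FLC for SDG25 remains a hypothesis, found and tested on the same arrays.

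HSL1 differed between backgrounds in its response to sdg26, with an interaction of -1.803 with sdg25 (adjusted p = 7.58e-08), since its level was near that of WT in each single mutant and lower in the double. AT3G56210 had an interaction of -1.40 there (0.0023), AT1G49790 of 1.27 (0.0364) and AT4G11970 of 0.988 (0.0346). AT1G49790 lost its call in 9 and AT4G11970 in 8 of 12 omissions of an array. Of 9 other ways of processing or modelling, 5 ended the call of AT1G49790 (normexp, quantile normalization, no filter on dim probes, the series matrix and slides as a fixed block) and 4 that of AT4G11970 (normexp, no filter on dim probes, the mean of probes and slides as a fixed block). For sdg25 with ldl1 ldl2, AT3G56210 stood at -1.532 (0.00047) and MRD1 at 2.688 (0.0203). MRD1 means were -0.55 in WT, -3.63 in sdg25, -2.54 in ldl1 ldl2 and -2.93 in the triple. Its call was lost as above, at most at 0.139 without ldl1 ldl2 sdg25 replicate 2. WT lay above every mutant array, which can give it.

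A dimmer probe of ATX1, which the gene's values do not use, was well above background on 0 of 3 WT arrays and on all 3 arrays of both atx1 lines. It was at least 3.62-fold higher in atx1 (adjusted p = 0.00989) and 4.28-fold in atx1 sdg26 (0.0033). The fitted log2 values, 1.925 and 2.168, rest on WT signals below background and give no size, while the brighter probe differed by -0.68 and -0.23.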

How the results depend on the processing

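The fit on the 17 arrays of scan days 1 and 2 and the histone list without the mutated genes were chosen after the data had been seen, and all other alternatives were planned. The cause of the changes below was not tested, except that omissions of arrays leave fewer samples, sometimes a pair that is assumed to vary like the other genotypes. Of 346 values of named genes, those that kept a call or, if not called, moved little were 241 with normexp, 330 with quantile normalization, 326 without the filter on dim probes, 310 with the mean of probes, 327 with the series matrix, 345 with the replicate block, 271 and 346 with slides as a fixed and a random block, 339 with scan day as a block and 135 on days 1 and 2 alone. No named gene changed sign while called. Of all genes called in the main test, some turned sign, called or not. With the mean of probes these were 16 in ldl1 ldl2 sdg25, 4 in ldl1 ldl2, 3 in clf sdg26, 2 each in sdg25, sdg25 sdg26 and clf, and 1 each in atx1 sdg26, ldl1 ldl2 sdg26 and the averaged effect. With normexp they were 11 in ldl1 ldl2 sdg25, 3 in atx1 sdg26, 2 each in atx1, ldl1 ldl2 and ldl1 ldl2 sdg26, and 1 each in sdg25, sdg26 and clf. Of 2358 such values with 1 array left out, 1875 stayed and 475 lost their call. Of 98 values of gene lists 18 kept their call with an estimated correlation or stayed without one, and 84, 88, 84, 83, 86, 81, 78, 85, 75 and 62 stayed under the alternatives in the order above; of 840 with 1 array left out 620 did. Of 18 correlations between backgrounds, 9 moved by more than the highest simulated value with normexp, 5 with quantile normalization, 14 without the filter, 3 with the series matrix, 16 and 15 with slides as fixed and random blocks, 14 with scan day and 17 on days 1 and 2. Signal over background limits the dim genes, for which only bounds are given.

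Counts of called genes follow in the order sdg25, sdg26, sdg25 sdg26, atx1, atx1 sdg26, clf, clf sdg26, ldl1 ldl2, ldl1 ldl2 sdg25 and ldl1 ldl2 sdg26 against WT, where they moved by over 1.5 times. Normexp gave 48, 11, 36, 23, 52, 179, 136, 253, 668 and 170. Against the parent lines it gave 10 for sdg25 sdg26 against sdg25, 4 for atx1 sdg26 against atx1, 6 for ldl1 ldl2 sdg26 against ldl1 ldl2, 8 for sdg25 sdg26 against sdg26 and 24 for ldl1 ldl2 sdg25 against ldl1 ldl2; the averaged sdg26 effect gave 87 and the interaction of sdg26 with sdg25 2. Quantile normalization gave 70 and the series matrix 69 for sdg26, and both gave 1 for the interaction of sdg26 with clf. Without the filter on dim probes the interaction with sdg25 had 2 genes, both lower. With the mean of probes atx1 sdg26 against atx1 had 4 genes and ldl1 ldl2 sdg26 against ldl1 ldl2 7.

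Without the mutated genes the mean of the histone list was 0.033 in ldl1 ldl2, 0.043 in ldl1 ldl2 sdg25, 0.015 in ldl1 ldl2 sdg26, -0.121 in clf sdg26 and -0.025 in sdg25 sdg26 against sdg25, none of them called. Normexp turned the mean of floral organ identity genes in atx1 sdg26 to -0.099. The mean of light-harvesting antenna genes became -0.04 in atx1 and -0.022 in clf after quantile normalization and -0.035 and -0.019 in the series matrix, and in the interactions of sdg26 with atx1 and clf 0.083 and 0.025, and 0.081 and 0.021. On days 1 and 2 the means turned for cell division genes in atx1 sdg26 against atx1 (-0.05) and sdg25 sdg26 against sdg26 (0.005) and for jasmonate genes in the averaged effect (-0.077). Light-harvesting genes in sdg25 sdg26 against sdg25 turned to -0.077 without sdg25 sdg26 replicate 3 and stood at 0.348 without sdg25 replicate 2. The median of all genes lay beyond ±0.1 on the log2 scale with normexp in atx1 sdg26 (-0.117) and the interactions of sdg26 with sdg25 (0.13), clf (0.107) and ldl1 ldl2 (0.103). Without the filter it was -0.11 in atx1, -0.13 in atx1 sdg26, -0.109 in clf, -0.108 in ldl1 ldl2, 0.134, 0.115 and 0.108 in those interactions and 0.102 in that of sdg25 with ldl1 ldl2.

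The replicate number as a block gave 633, 552, 339, 1295, 1716, 1863, 1184, 2108, 3017 and 801 genes against WT. It gave 47 for sdg25 sdg26 against sdg25, 27 for atx1 sdg26 against atx1 (6 up and 21 down), 10 for clf sdg26 against clf, 23 for ldl1 ldl2 sdg26 against ldl1 ldl2, 31 for sdg25 sdg26 against sdg26, 71 for ldl1 ldl2 sdg25 against ldl1 ldl2, 369 for the averaged effect and 8 for the interaction of sdg26 with clf. Deviations from the genotype means had a median correlation of 0.347 between arrays with the same number and -0.207 between others, beside 0.358 and -0.183 for the same and other scan days. The labels do not say that a number marks a shared day, and of the 30 pairs of a WT and a mutant array with the same number 9 had deviations that correlated over 0.1, from -0.328 to 0.338, so the numbers are not taken to pair the arrays. Each array's best match carried its own number in 29 of 33 cases, a hint from the data.

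Slides as a fixed block gave 318 for sdg25, 310 for sdg25 sdg26, 24 for atx1, 10 for atx1 sdg26, 156 for clf (92 up and 64 down), 93 for clf sdg26 (58 up and 35 down) and 916 for ldl1 ldl2 sdg26; 18 for atx1 sdg26 against atx1 (3 up and 15 down), 3 for clf sdg26 against clf, 6 for ldl1 ldl2 sdg26 against ldl1 ldl2, 8 for sdg25 sdg26 against sdg26, 76 for ldl1 ldl2 sdg25 against ldl1 ldl2 and 2 for the interaction with sdg25. As a random block, with a consensus correlation of 0.434, they gave 671 for sdg25, 252 for sdg26, 498 for sdg25 sdg26, 250 for atx1, 194 for atx1 sdg26, 1319 for ldl1 ldl2, 2272 for ldl1 ldl2 sdg25 and 1263 for ldl1 ldl2 sdg26. In the order of parent comparisons above, the random block gave 72, 46 (10 up and 36 down), 11, 19, 46 and about 1.1e+02 (44 up and 63 down), and 446 for the averaged effect, 8 and 6 for the interactions of sdg26 with sdg25 and clf and 7 for that of sdg25 with ldl1 ldl2. Scan day as a block gave 434, 87, 446, 284, 215, 1016, 1292, 2178 and 943, with clf at 458 within 1.5 times. It gave 51 for sdg25 sdg26 against sdg25, 36 for atx1 sdg26 against atx1, 37 for sdg25 sdg26 against sdg26, 83 for ldl1 ldl2 sdg25 against ldl1 ldl2, 485 for the averaged effect and 8, 1 and 6 for those 3 interactions. The arrays of days 1 and 2 alone gave 5, 0, 4, 20, 0, 31, 48, 85, 42 and 91 against WT, 2 for sdg25 sdg26 against sdg25, 1 for atx1 sdg26 against atx1, 0 for clf sdg26 against clf, 1 for sdg25 sdg26 against sdg26, 0 for ldl1 ldl2 sdg25 against ldl1 ldl2, 7 for the averaged effect and 0 for the interactions of sdg26 with sdg25 and of sdg25 with ldl1 ldl2.

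With 1 array left out the counts against WT lay between 56 and 324, 1 and 222, 53 and 215, 14 and 615, 10 and 253, 109 and 530, 144 and 617, 169 and 1146, 359 and 1753, and 167 and 425, in the order above. The highest count came without WT replicate 3 in all 10. Against parents they lay between 9 and 18, 2 and 4, 5 and 7, 4 and 7, 8 and 10, and 20 and 31, for the averaged effect between 149 and 215, and for the interactions of sdg26 with sdg25, atx1, clf and ldl1 ldl2 and of sdg25 with ldl1 ldl2 between 2 and 11, 0 and 2, 0 and 2, 0 and 2, and 2 and 5.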

Other observations

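Of the tests in this part, those of levels in WT and of genes near the mutated loci were chosen after the results had been seen; the counts over other splits of the arrays were planned. Some genes named by the rule moved in opposite directions in different mutants. AT5G56370 fell by 1.83 on the log2 scale in sdg25 (adjusted p = 0.000107, limma) and by 1.42 in sdg25 sdg26 (0.00374), and rose by 2.11 in clf (5.68e-06) and 2.404 in clf sdg26 (4.3e-07). AT3G54730 fell by 2.08 in clf (0.000375) and 1.87 in clf sdg26 (0.00133), and rose by 2.68 in ldl1 ldl2 (1.31e-05) and 2.54 in ldl1 ldl2 sdg25 (1.58e-05). AT1G77960 fell by 1.52 in sdg25 (0.00117) and rose by 2.51 in ldl1 ldl2 sdg26 (2.31e-07). All these calls held without each single array. The mean of probes ended that of AT5G56370 in sdg25 sdg26 (0.173) and slides as a fixed block that of AT3G54730 in clf sdg26. The values with scan day as a block were -1.74, -1.17, 2.44 and 2.50 for AT5G56370, -1.78, -1.81, 2.98 and 2.84 for AT3G54730 and -1.62 and 2.51 for AT1G77960. The dehydrin gene LTI30 rose by 1.74 in ldl1 ldl2 sdg25 (0.0024), and AT4G29370 was at least 13.9-fold and 12.2-fold higher in ldl1 ldl2 sdg25 and ldl1 ldl2 sdg26 (1.2e-05 and 2.53e-05).

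The probe-level fit covered 32814 probes, 4956 of them without a matched gene. Unmatched probes made up 60 of 258 called probes in sdg25, 12 of 55 in sdg26, 46 of 201 in sdg25 sdg26, 34 of 176 in atx1, 26 of 133 in atx1 sdg26, 58 of 378 in clf, 83 of 471 in clf sdg26, 98 of 636 in ldl1 ldl2, 242 of 1613 in ldl1 ldl2 sdg25 and 76 of 461 in ldl1 ldl2 sdg26.

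Of 19624 genes, 96 had levels on all 3 WT arrays outside those of all 30 mutant arrays, 62 higher and 34 lower. A share of 0.885 of them, 85 genes, passed for the mean of the mutants with scan day as a block, beside 82 without it, but these genes were picked for WT levels outside those of mutant arrays of the same scan days too, so this restates the choice and scan day stays open. Dim probes as the whole cause are argued against, because a share of 0.906, 87 genes, were well above background on all arrays of one side. Chance ordering of arrays stays open as well: 99 draws of 3 arrays from different genotypes gave up to 132 such genes (median 2; the highest draw held 3 arrays of a single scan day) and 99 draws from the scan days of WT up to 94 (median 6), where the second set of draws and a margin of 1.5-fold were set after the values had been seen. By the same count ldl1 ldl2 sdg25 had 80 genes and the other mutants 3 to 37, so a state of the WT seedlings that may differ from all mutants is a hypothesis that these arrays cannot decide.

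Called genes were counted near the mutated loci, to test for a segment linked to the mutation, which would change genes there. Within 100 tested genes on either side there were 1 near SDG25 in sdg25, 0 near SDG26 in sdg26, 3 near ATX1 in atx1, 7 near CLF in clf, and 5 near LDL1 and 8 near LDL2 in ldl1 ldl2. At random places 95% of counts were at most 4, 2, 3, 7, 9 and 9, so none exceeded it, with ATX1 and CLF at that bound. A linked segment that changes more genes than this is argued against, but the count says little of the closest genes. AT3G13674, 1 gene from LDL2, differed by -0.857 (0.0146) and AT3G13650, 3 genes away, by -0.949 (0.0282), as 7 of the 8 near LDL2 were lower, and ASP4, 3 genes from LDL1, by 0.896 (0.00741), so an effect of the mutated locus on them stays open.

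Other splits of the arrays into groups of the same sizes were counted with limma. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and in each of the 16 such comparisons only the real split, 1 of 10, reached its count. The highest count of another split was 0, 1, 3, 1, 10, 0, 4, 0, 10 and 4 against WT, in the order sdg25, sdg26, sdg25 sdg26, atx1, atx1 sdg26, clf, clf sdg26, ldl1 ldl2, ldl1 ldl2 sdg25 and ldl1 ldl2 sdg26, beside the real 131, 42, 137, 119, 96, 329, 360, 517, 1217 and 334. Against the parents it was 1 (real 20) for sdg25 sdg26 against sdg25, 0 (real 2), 0 (real 6) and 0 (real 12) for atx1 sdg26, clf sdg26 and ldl1 ldl2 sdg26 against their parents, 1 (real 17) for sdg25 sdg26 against sdg26 and 0 (real 38) for ldl1 ldl2 sdg25 against ldl1 ldl2. For the averaged sdg26 effect only the real split of 100 reached 200 genes (highest other 1), which argues against chance. For the interactions 5 of 100 splits reached the 4 genes of sdg26 with sdg25 (highest other 17) and 12 the 3 genes of sdg25 with ldl1 ldl2 (3073), and all 100 reached the 0 genes of sdg26 with atx1, clf and ldl1 ldl2 (34, 61 and 3841). With shares of at least 0.05, chance stays open for the counts of 4 and 3 genes. These splits mix genotypes that differ in many genes, as 3073 and 3841 point to, and any split reaches 0 genes. The interaction calls of HSL1 and FLC held in all 12 omissions of an array and under all 9 other ways of processing or modelling that were set beforehand.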
